A study of Mus musculus with 2 samples.

How the data were processed

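The series holds 2 libraries from cultured peritoneal macrophages of SV129 mice, 1 of input RNA and 1 of RNA purified with a biotin-labelled miR-1 oligonucleotide, sequenced on the Illumina HiSeq platform per the labels' protocols. The submitters' processing notes name bcl2fastq, TopHat2 2.0.14, Cuffnorm and the mouse build mm10 (GRCm38), with no role or order. The program that counted reads, the annotation, the handling of strand and of reads with several matches, and the test behind the p-values are not given in the sources used here. The molecule measured is total RNA per the labels, and neither an RNA selection step nor a step to remove DNA is given in the sources used here.

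The analysis used 1 table of the authors, which lists 18499 genes by Entrez ID. The counts deposited by the authors are whole reads per gene, not normalized, and they sum to 317290 in the input and 734136 in the pull-down. The RPKM values deposited by the authors are reads scaled by the listed gene length and by those totals. Recomputed from counts and length, the RPKM was the same within a relative 0.001 for 18354 genes, while 145 genes had a value that the listed length does not give. The authors set the RPKM of a gene with 0 reads to 0.001, and it was taken as 0 here. The log2 ratio deposited by the authors is that of the deposited RPKM values, the 0.001 included. The p-value column deposited by the authors and its FDR come from a comparison of the 2 libraries. The FDR column was treated as a score, since the authors' deposited table has 325 genes with an FDR above 1, the largest 1.02, and only its calls at 0.05 were counted.

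Each gene listed had at least 1 read in 1 of the libraries, so a gene with 0 input reads always has pull-down reads here. Depth was low: for a gene of 3 kilobases, 1 RPKM is 0.952 reads in the input and 2.20 reads in the pull-down. A count of 0 allows up to 3 reads, which is 0.000946% of the input reads and 0.000409% of the pull-down reads.

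Symbols and GRCm38 coordinates came from the RefSeq table of assembly GRCm38.p6, where 18454 Entrez IDs matched and 45 did not. The groups were taken from the labels. With 1 library per group no test across samples, leave-one-out or split of the samples was possible, and no p-value was computed. The main value was log2 of (pull-down RPKM + 1) over (input RPKM + 1). A gene was called higher or lower when this was at least 1 either way and the higher library had at least 1 RPKM. This scale understates the ratio of low genes, so folds in the text are ratios of RPKM. Their 95% intervals come from the exact Clopper-Pearson interval of the pull-down share of the gene's reads, and folds against 0 reads were taken against 3 reads. For such a fold, "at least" refers to this 3-read floor alone. The count of the other library is taken as exact, so the 95% interval can reach closer to 1 than the fold given. The 24 gene lists, the rule for named genes, the seed sites and the alternatives were fixed before the data were examined, except where the text says otherwise. The lists are from textbook knowledge, and older symbols were matched where no current gene has the listed symbol. The list of 28 mitochondrially encoded gene symbols had no member in the table and gives no result. Each list's median was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries.

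Named genes were the 12 highest and 12 lowest log2 ratios among genes with at least 5 RPKM in the higher library and 50 reads over both, the 2 highest and 2 lowest members of each list, Stat1, Caprin1, Ifngr1, Ifngr2, Jak1, Jak2, Sros1 and Ago2, reported miR-1 targets at least 2-fold higher, and the 10 most abundant genes of each library. Xist was named after its values were seen. Of each of these groups the text gives a part, and the rest are in the counts. Seed sites of miR-1 were searched in the longest annotated 3' UTR of each gene in GENCODE release M21, which covers 16888 of the listed genes, and in coding sequences and whole transcripts. The seed result was also set beside 209 other words of 7 bases with the same composition.

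Alternatives were a pseudocount of 0.1, other filters on low values, centring on the median log2 ratio, TMM factors from edgeR 4.0.16 on the counts, a log2 ratio of 2, other matching of the random lists and other sites. Chosen after the data were seen were leaving out the most abundant input feature from the library totals, matching on input expression alone, and searching whole transcripts. Against the deposited scaling, leaving out that feature moves each log2 ratio of RPKM by −0.70, centring by −0.14 and TMM by −0.05, and the main list medians keep their sign under these except that of the microRNA pathway. The 135 genes at 100 RPKM or more in the pull-down held 37.6% of its reads and 46.1% of input reads. Among them, the most abundant input feature alone held 42.1% of input reads and 5.76% of pull-down reads. Scaling without the 135 genes was not run. Single genes whose interval changes its side of 1 without the most abundant input feature are named where the text gives them. Bootstrap ranges are the central 95% of 2000 draws over genes and describe these libraries only.

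The scripts were tested on simulated counts for the 18499 genes with 200 changed genes, 50 per fold size. The changed genes were drawn from the 2425 genes with at least 20 expected input reads. Recovery and interval coverage were thus not tested for genes with few or 0 input reads. Of the changed genes, 96.0% with a true fold of 2, 92.0% with 4, 88.0% with 0.5 and 74.0% with 0.25 came out within 0.5 log2. The counting interval held 95.1% of the true ratios over 2425 genes, and 4.0% of 200 random lists lay outside the central 95%. The latter share follows from drawing those lists from the same genes as the comparison lists. Apart from the changed genes, both simulated libraries had the same mean levels, unlike the uncorrelated libraries of the series. The simulation thus cannot show how matching on mean expression acts on lists of genes high in the input. A simulated X chromosome at 0.5 of the autosomes came out at 0.509. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.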

Results

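Peritoneal macrophages, phagocytes of the abdominal cavity, were taken from SV129 mice and cultured. RNA bound to a biotin-labelled miR-1 oligonucleotide was purified from these cells (here called the pull-down) and sequenced beside the input RNA. The comparison asked which transcripts miR-1, a microRNA best known from heart and skeletal muscle, binds in macrophages. There was 1 input library and 1 pull-down library, so no difference below has a replicate check, and no test across samples was possible. The input library held 317290 reads over the 18499 genes listed and the pull-down held 734136. Reads fell on 8563 genes in the input and on 17497 in the pull-down, and a gene of 20 or more reads was found 1700 times in the input against 7679 times in the pull-down. A single feature, Entrez ID 100861531, which had no name in the reference tables, took 42.1% of the input reads (Wilson 95% interval 41.9% to 42.3%) and 5.76% of the pull-down reads (5.71% to 5.81%). The intervals, and the floor of 3 reads used for a library with 0 reads, cover counting error only. A fold given as "at least" is taken against that floor with the other count as exact, so its 95% interval can reach closer to 1.

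The transcripts that filled the input of these macrophages were far lower in the pull-down, and 9936 genes with no input read were present in it. Psap, the precursor of the lysosomal saposins, was 90.6-fold lower in the pull-down (5996 against 66.2 RPKM). Lyz2, the macrophage lysozyme, was 129-fold lower (4482 against 34.8 RPKM). Cd14, the lipopolysaccharide co-receptor, had 282 reads in the input and 0 in the pull-down, at least 217-fold lower. Kcne1, a cardiac potassium channel subunit, had 0 input reads and 164 pull-down reads, at least 23.6-fold higher. Of 17956 genes with at least 1 RPKM in either library, 11846 were at least 2-fold higher in the pull-down on the log2(RPKM + 1) scale, 3122 were at least 2-fold lower and 2988 lay between. Of the 11846, 9410 had 0 input reads, and for 7581 the counting interval of the ratio lay above 1. Of the 3122, 996 had 0 pull-down reads, and for 2306 the interval lay below 1. With 50 or more reads over both libraries, 2256 genes were higher and 709 were lower. Across all 18499 genes, which are not independent replicates, the libraries were uncorrelated on the log2(RPKM + 1) scale (Pearson r −0.04, Spearman rho −0.06). With a pseudocount of 0.1, r was −0.13. No gene listed had 0 reads in both libraries, which can lower these values. Over the 6937 genes at 1 RPKM or more in both, r was 0.15.

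**Figure D1:**
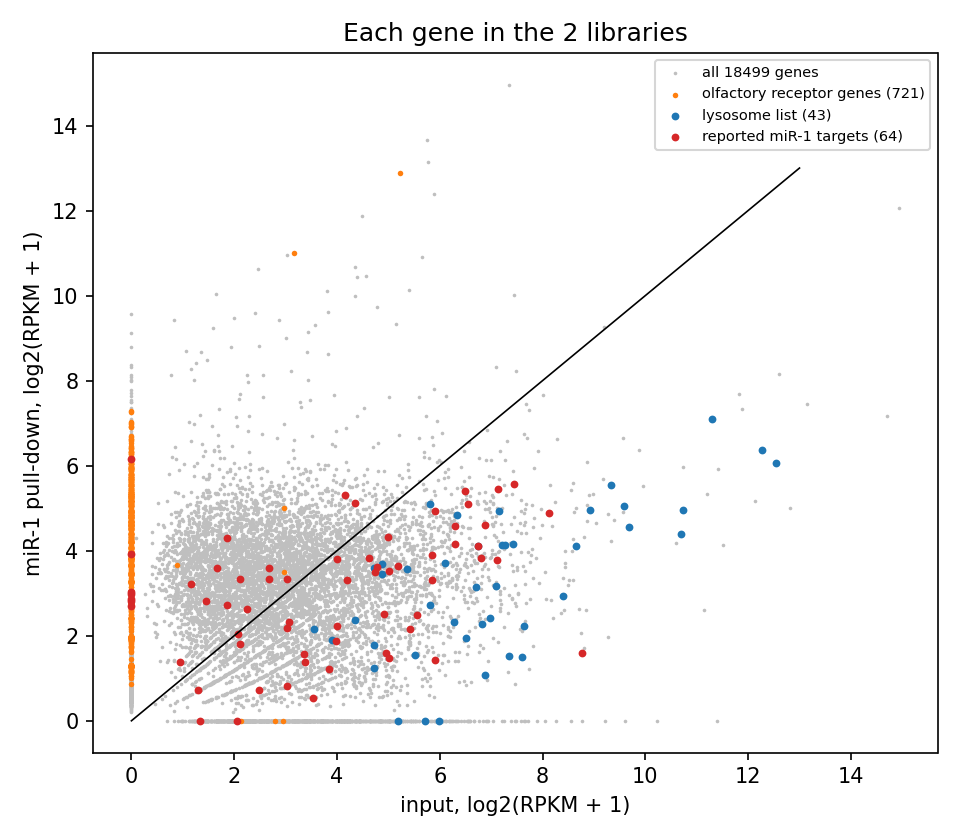
Each point is 1 of the 18499 genes, placed by log2(RPKM + 1) in the input (horizontal axis) and in the miR-1 pull-down (vertical axis), with the line of equal values. The 43 lysosome genes (blue) lie below the line, the 721 olfactory receptor genes (orange) lie mostly at 0 in the input, and the 64 reported miR-1 targets (red) lie on both sides.

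Messenger RNAs reported as miR-1 targets in muscle, heart, fibroblast and cancer cells were mostly lower in the pull-down than in the input. Of 64 with a value, 13 were at least 2-fold higher, 34 were at least 2-fold lower and 17 lay between, with a median log2 ratio of −1.19, or −1.03 with 0 reads set to the 3-read floor. Kcne1 was the highest. Dll1, a Notch ligand, had 0 input reads and 36 pull-down reads, at least 5.19-fold higher. Notch3 (0 against 40 reads), Sox6 (0 against 35), Pax7 (0 against 19), Pax3 (0 against 18) and Klf4 (0 against 16) also had no input reads. Among targets with input reads, Foxp1 was 7.06-fold higher (6 against 98 reads, 95% counting interval 3.13 to 19.7). Cdk9, a kinase of transcription elongation, was 2.31-fold higher (18 against 96 reads, interval 1.38 to 4.05). Ccnd2 was 5.08-fold higher, Bcl2 3.46-fold and Frs2 2.74-fold. With the most abundant input feature left out of the totals, the intervals of Cdk9 (0.850 to 2.49), Bcl2 (0.754 to 8.27) and Frs2 (0.706 to 4.87) included 1. Ets1, with 2 input reads, had a ratio of 6.70 (interval 1.70 to 57.8). At the other end, Tmsb4x, which encodes the actin-sequestering thymosin beta 4, had 92 input reads and 1 pull-down read, a ratio of 0.0047 (interval 0.000118 to 0.0268). Cap1 had 45 and 3 reads, a ratio of 0.0288 (0.00573 to 0.0898). The median of the list lay below all 10000 random lists matched on mean expression, whose central 95% ran from −0.24 to 1.49. Against random lists matched on input expression alone it lay at percentile 15.8.

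Stat1, the transcription factor of the interferon-gamma response named in the title of the series, had 22 reads in the input and 5 in the pull-down. Its RPKM was 13.4 against 1.31, 10.2-fold lower (ratio 0.0982, interval 0.0291 to 0.266). The gene lies on chromosome 1 at 52119438 to 52161865 of GRCm38. Caprin1, an RNA-binding protein (chromosome 2, 103762945 to 103797669), was 9.06-fold lower, with 47 against 12 reads. The interferon-gamma receptor genes Ifngr1 (10 against 8 reads) and Ifngr2 (62 against 5 reads) were 2.89-fold and 28.7-fold lower. Jak2 was 28.9-fold lower (50 against 4 reads), and Jak1 (36 against 70 reads) had an interval from 0.555 to 1.29, or 0.341 to 0.795 with the most abundant input feature left out of the totals. The long non-coding RNA Sros1 was not listed under that symbol and has no value here. Of 23 interferon-gamma and JAK-STAT pathway genes, 1 was at least 2-fold higher, Ciita, with 2 against 55 reads and a ratio of 11.9 (interval 3.14 to 101). Of the others, 11 were lower and 11 lay between, and the median of −0.72 was inside the random lists at percentile 4.7.

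Interferon-stimulated genes were split. Of 41, 9 were higher, 17 were lower and 15 lay between, with a median of −0.11 at percentile 6.09. Oas2, a sensor of double-stranded RNA, was 18.5-fold higher with 4 against 171 reads, and Iigp1 was at least 3.60-fold higher with 0 against 25 reads. Ifitm3 had 14 against 0 reads, at least 10.8-fold lower, and the immunoproteasome gene Psmb8 had 11 against 0 reads, at least 8.48-fold lower. Inflammatory cytokines and chemokines were lower for 16 of 29 genes and higher for 8, with a median of −1.51. Cxcl2 (129 against 0 reads) was at least 99.5-fold lower and Ccl4 (43 against 0 reads) at least 33.2-fold lower, while Nos2 had 0 against 22 reads, at least 3.17-fold higher. Ccl12 had 0 against 3 reads, too few for a ratio. Toll-like receptor and NF-kappaB genes were lower for 14 of 36 and higher for 8, with a median of −0.77. Tlr2 was 57.8-fold lower (175 against 7 reads), and Tlr9 (0 against 53 reads) and Tlr4 (0 against 24 reads) were at least 7.64-fold and 3.46-fold higher. The cytokine list lay at percentile 0.04 and the Toll-like receptor list at percentile 0.4 of random lists matched on mean expression, and at 17.8 and 41.1 when lists were matched on input expression alone.

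Genes of the macrophage itself were among the lowest. Of 43 lysosome genes, 42 were at least 2-fold lower in the pull-down, 1 lay between and 0 were higher, with a median of −3.95, or −3.79 at the floor. Ctsl, a lysosomal cysteine protease, was 82.9-fold lower, while Ctsk (26 against 36 reads, interval 0.351 to 1.03, or 0.216 to 0.634 without the most abundant input feature) was the highest member. Of 30 macrophage markers 20 were lower, 6 were higher and 4 lay between, with a median of −3.02. Trem2 had 76 against 0 reads, at least 58.6-fold lower. Garnl3 had 0 against 25 reads, at least 3.60-fold higher. Icam2, with 1 against 14 reads, had a ratio of 6.05 (interval 0.921 to 256). Both lists lay below the central 95% of random lists, matched on mean or on input expression.

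Markers of cells other than macrophages were mostly higher in the pull-down, as were 66.0% of all genes with at least 1 RPKM. Of these lists only that of granulocytes and mast cells lay outside the random lists matched on mean expression, at percentile 98.1, and it came inside when lists were also matched on gene length (percentile 96.3). The others lay inside, at percentile 71.8 for T and NK cells, 94.8 for striated muscle, 90.0 for red cells and platelets, 93.1 for dendritic cells, 7.87 for B cells and 32.7 for mesothelial and stromal cells. Members with 0 input reads numbered 9 of 13 for T and NK cells, 13 of 15 for muscle, 13 of 15 for granulocytes and mast cells, 9 of 9 for red cells and platelets, 5 of 9 for dendritic cells, 7 of 10 for B cells and 3 of 14 for mesothelial and stromal cells. For T and NK cells 12 of 13 genes were higher, among them Klrb1c (0 against 77 reads, at least 11.1-fold) and Cd3d (0 against 28 reads, at least 4.03-fold), with a median of 3.40. The lowest were Cd247 (2 against 4 reads, interval 0.124 to 9.56) and Cd5 (1 against 7 reads, ratio 3.03, interval 0.389 to 136). For Cd247 the ratio of the deposited RPKM values, 1.52, is not the one its reads give, so its direction is uncertain. For striated muscle 14 of 15 were higher, with a median of 3.56. Mylpf, a myosin light chain, had 0 against 17 reads, 2.45-fold higher against the 3-read floor (95% interval from 1.78). Mb, myoglobin, had 0 against 15 reads, 2.16-fold higher against the floor (interval from 1.55). For Mb the fold was 1.33 and the interval started at 0.953 without the most abundant input feature. Des had 10 against 2 reads with a ratio of 0.0864 (interval 0.00921 to 0.406). For granulocytes and mast cells 14 of 15 were higher with a median of 2.75, including Cpa3 (0 against 42 reads, at least 6.05-fold) and Mcpt4 (0 against 23 reads, at least 3.31-fold). All 9 red cell and platelet genes were higher by this rule with a median of 3.03, although Hbb-bs rested on 0 against 2 reads, too few for a ratio. Of 9 dendritic cell genes 6 were higher, Siglech with 0 against 73 reads (at least 10.5-fold), and 2 were lower, Itgax 6.47-fold with 221 against 79 reads. Of 10 B cell genes 7 were higher, such as Cd19 (0 against 15 reads, 2.16-fold against the floor, interval from 1.55). Without the most abundant input feature its fold was 1.33 and its interval started at 0.953. Mesothelial and stromal genes were divided, with 7 of 14 higher and 4 lower. Msln had 0 against 22 reads, at least 3.17-fold higher, and the collagen gene Col1a2 was 160-fold lower (345 against 5 reads). With genes of 0 reads set to the 3-read floor, the medians were lower: 1.22 for T and NK cells, 1.03 for muscle, 0.34 for granulocytes and mast cells (−0.30 without the most abundant input feature), 1.54 for dendritic cells, 0.66 for mesothelial and stromal cells, −0.17 for red cells and platelets and −0.25 for B cells. A pseudocount of 0.1 raised them to 6.59 for T and NK cells, 6.77 for muscle, 5.86 for granulocytes and mast cells and 7.32 for dendritic cells. The values were 1.33 for mesothelial and stromal cells, 6.19 for red cells and platelets and 4.47 for B cells. The size of these medians thus rests on how 0 reads are treated.

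Several housekeeping groups and the immediate early genes were mostly lower. Of 66 nuclear genes of oxidative phosphorylation, 46 were lower and 7 higher, with a median of −2.65. As 27 of the 66 had 0 pull-down reads, the median was −1.50 with 0 reads set to the floor. Cox6a1 and Atp5g3 each had 20 against 0 reads, at least 15.4-fold lower. Of 75 ribosomal protein genes 50 were lower and 8 higher, with a median of −1.70, or −1.83 at the floor. Rps19 (33 against 0 reads) was at least 25.5-fold lower, while Rpl27 was 6.81-fold higher (4 against 63 reads). Ribosomal protein genes have many pseudogene copies that could share reads, so single values of this group are uncertain. Actin cytoskeleton genes were lower for 38 of 47 (median −2.05, or −1.88 at the floor), Lcp1 by 49.0-fold, and higher only for Myl12b, with 3 against 39 reads and a ratio of 5.62 (interval 1.79 to 28.4). Proteasome genes were lower for 18 of 31 (median −1.36, or −0.88 at the floor), with Psmb6 (33 against 0 reads) at least 25.5-fold lower. Immediate early genes were lower for 14 of 26 (median −1.20, or −1.01 at the floor), and Ier3 (35 against 0 reads) was at least 27.0-fold lower, while Fosb (0 against 26 reads) was at least 3.75-fold higher. Glycolysis and pentose phosphate genes were lower for 13 of 24 (median −1.11, percentile 10.5), Pgd by 10.7-fold and Aldoa by 9.35-fold, while Aldoc (0 against 66 reads) was at least 9.51-fold higher. Except for glycolysis, these groups lay below the central 95% of random lists matched on mean expression. Matched on input expression alone, oxidative phosphorylation stayed below at percentile 0.02, proteasome (20.2), actin (76.3) and immediate early genes (28.1) lay inside, and ribosomal protein genes lay above at percentile 99.97.

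**Figure D2:**
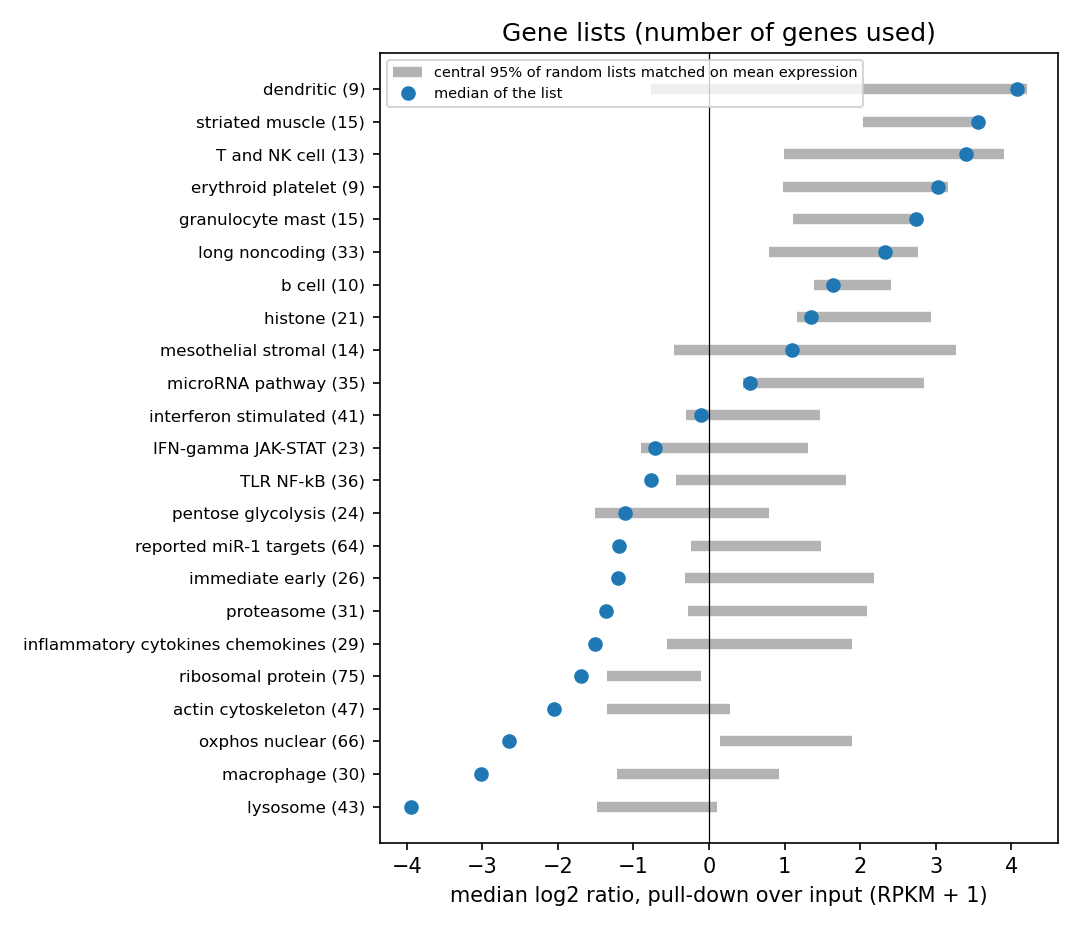
Points give the median log2 ratio of pull-down over input for each of 23 gene lists, with the number of genes used in brackets, and grey bars give the central 95% of 10000 random lists matched on mean expression. The lysosome list is the lowest at −3.95 and the dendritic cell list the highest at 4.08, with 10 lists outside their bars on the low side and 1 on the high side.

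Small and long non-coding RNAs went both ways. Rpph1, the RNA of ribonuclease P, had 276 against 0 reads, at least 213-fold lower, and Rn7sk, which restrains transcription elongation, was 185-fold lower (26628 against 144 RPKM). Rn28s1 was 233-fold lower and Rmrp 52.3-fold lower. Of 33 listed non-coding RNAs, 25 were higher, 5 were lower and 3 lay between, with a median of 2.33, or 1.05 with 0 reads set to the floor. The median lay inside the matched random lists, at percentile 77.2, and 66.0% of all genes with at least 1 RPKM were higher. Mirg had 0 against 31 reads, at least 4.47-fold higher, and Epb41l4aos had 0 against 8 reads. Genes of the microRNA pathway had a median of 0.54, which was −0.06 when the most abundant input feature was left out of the library totals. Ago2, the slicing Argonaute protein, was 3.26-fold lower (69 against 49 reads), and Cnot7 (18 against 0 reads) was at least 13.9-fold lower. Dcp1a, with 2 against 86 reads, had a ratio of 18.6 (interval 4.99 to 156), and Prkra (0 against 20 reads) was at least 2.88-fold higher. Of 35 genes in this list 14 were higher and 8 lower, at percentile 3.55, inside the random lists. Histone genes were higher for 13 of 21 and lower for 8, with a median of 1.36, or −0.58 at the floor, and lay inside the matched random lists at percentile 9.11. H1f2 had 14 against 0 reads, at least 10.8-fold lower, and H4f16 had 1 against 868 reads, a ratio of 375 (interval 67.2 to 14834).

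The highest values of the pull-down belonged to few genes. 4930470H14Rik reached 31816 RPKM with 40501 reads, against 162 RPKM and 89 reads in the input, 197-fold higher. It lies on chromosome 17 at 4044658 to 4082995 of GRCm38. Gm17644 was 242-fold higher with 30256 reads, the zinc finger gene Zfp488 169-fold with 28513, Olfr856-ps1 207-fold with 9085 and Olfr613 256-fold with 7692. Ccdc82 was 39.2-fold higher (73 against 6626 reads). How reads with several matches were counted is not given in the sources used here, so the values of such genes are uncertain. Ranked by log2 ratio, Mir680-2 (0 against 61 reads) was at least 8.79-fold higher, C330024D21Rik (0 against 1128) at least 163-fold, Csprs (0 against 880) at least 127-fold and Gjc3 (0 against 852) at least 123-fold. Zfp781, with 1 against 2045 reads, had a ratio of 884 (interval 158 to 34927). At the low end, Cyba, a subunit of the phagocyte oxidase, had 188 against 0 reads and was at least 145-fold lower. The translationally controlled tumour protein gene Tpt1 (132 against 0) was at least 102-fold lower, Txn1 (66 against 0) at least 50.9-fold and Spp1, osteopontin (92 against 0), at least 71.0-fold. Saa3, an acute-phase protein gene, had 378 against 2 reads and a ratio of 0.00229 (interval 0.000276 to 0.00832).

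Genes with a match to the miR-1 seed did not lie above matched random lists under any setting run. With the match in the 3' UTR they lay below them only with a pseudocount of 0.1, and those with it in the coding sequence or whole transcript also lay below. The search used the miR-1 sequence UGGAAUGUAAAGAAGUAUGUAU and, for its bases from the second to the eighth, the site ACATTCC. Of 16401 genes with an annotated 3' UTR and at least 1 RPKM, 1914 had the site. Their median log2 ratio was 1.66, at percentile 9.33 of random lists matched on mean expression (central 95% 1.62 to 1.87). The 714 genes with the longer site ACATTCCA had a median of 1.59 at percentile 11.2, and the 5586 genes with the shorter site CATTCC a median of 1.73 at percentile 14.1. Of 209 other words with the same bases, 190 had a higher mean ratio after adjustment for expression and 3' UTR length, and its residual of −0.52 lay within the central 95% of theirs (−0.56 to −0.25). In the pull-down alone 91 of the 209 were higher after adjustment for 3' UTR length. In the pull-down alone, genes with the site ACATTCC had a median of 8.44 RPKM and those without it 7.83 RPKM. With the site searched in the coding sequence, 1740 genes lay below the random lists, at percentile 1.29 with a median of 1.81. With a pseudocount of 0.1 the 3' UTR site lay below the random lists at percentile 0.93, over whole transcripts the site lay below at percentile 0.26, and with lists matched on input expression alone the 3' UTR site lay inside at percentile 92.8.

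The level of a gene in the pull-down varied little with its input level up to 50 RPKM and differed by chromosome, in splits chosen after the data were seen. The 9936 genes with 0 input reads had a median of 8.08 pull-down RPKM; as each gene listed had a read in at least 1 library, none of them was at 0. Genes above 5 to 20 RPKM in the input had a pull-down median of 6.84, those above 20 to 50 RPKM one of 8.01, and the 113 genes above 200 RPKM, such as Psap and Lyz2, a median of 20.5. Autosomal genes had a pull-down median of 7.89 RPKM, from 6.90 on chromosome 18 to 8.63 on chromosome 7. The 586 X-linked genes had a median of 3.89, a ratio of 0.493, below all 10000 random lists matched on gene length (central 95% 6.88 to 8.67). The 14 Y-linked genes had a median of 4.02. In the input, X-linked genes with at least 5 reads had a median of 12.1 RPKM (128 genes) and autosomal ones 13.5 RPKM (4799 genes), a ratio of 0.90, and in these genes, which were picked by their input reads, the pull-down ratio was 0.436. Over all listed genes the mean input RPKM was 7.99 on the X and 14.2 on autosomes, a ratio of 0.564 (bootstrap over genes 0.369 to 0.828). Xist, the RNA that coats the inactive X, had 0 input reads and 122 pull-down reads. These counts are not scaled by gene length, unlike the RPKM values above.

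**Figure D3:**
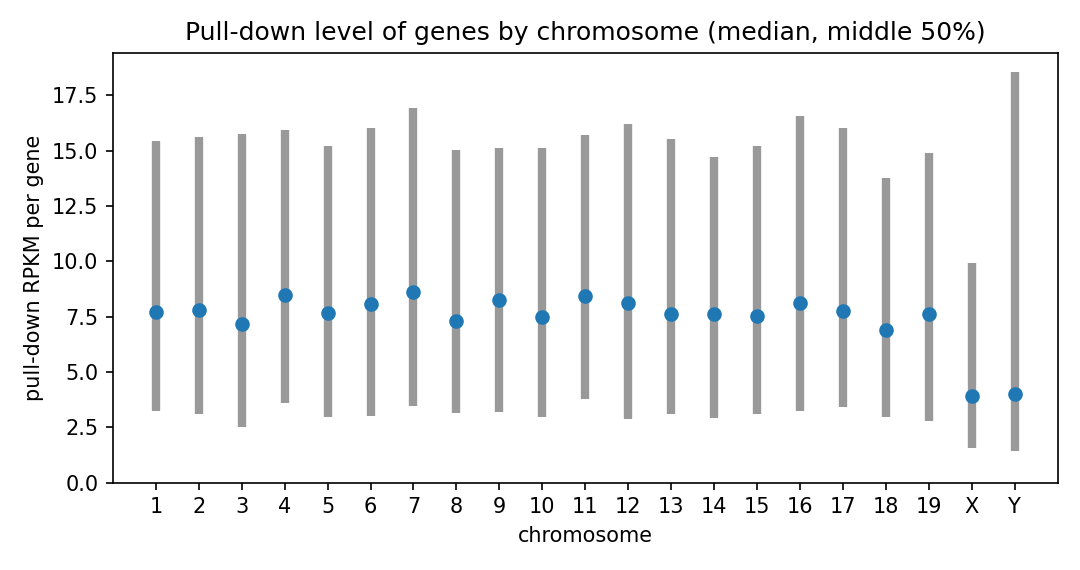
Points give the median pull-down RPKM of the listed genes on each chromosome and grey bars the middle 50% of genes. The 19 autosomes lie between 6.90 and 8.63 and the X and Y chromosomes at 3.89 and 4.02.

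The authors' deposited table lists 13902 genes as up in the pull-down and 4597 as down. At an FDR of at most 0.05, the authors' deposited table calls 7464 genes up and 2522 down. Of those 7464 genes in the authors' deposited table, 5491 had 0 input reads. A test on the reads of 2 libraries compares those libraries, not the conditions.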

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

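Matching on input expression alone, whole-transcript sites and leaving out the most abundant input feature were chosen after seeing the data. Of 140 alternatives, 121 left a result on its side of the limit or its value near the main one (counts within 1.5 times). Centring the lists cannot move a percentile and is not counted. Dropping the filter on low values is counted among the 121, although it cannot change the calls. A log2 ratio of 1 on the RPKM + 1 scale already needs at least 1 RPKM. Requiring 50 reads over both libraries gave 2256 higher and 709 lower genes, since fewer genes were counted (3716), and a log2 ratio of 2 gave 8953 higher and 1912 lower. Leaving out the most abundant feature gave 11176 higher and 4022 lower genes, 73.5% of calls on the higher side. Over genes at 1 RPKM or more in both libraries Pearson's r was 0.15. Matched on input expression alone, the medians of the reported miR-1 targets (−1.19), cytokines (−1.51), Toll-like receptor genes (−0.77), proteasome (−1.36), actin (−2.05), immediate early (−1.20) and granulocyte and mast cell genes (2.75) came inside the random lists. Red cell and platelet genes (3.03) then lay below them, muscle genes (3.56) above, and ribosomal protein genes (−1.70) turned from below to above. These changes come from the comparison lists, as the medians are those of the main setting. Granulocyte and mast cell genes also came inside when matched on gene length (2.75) and without the most abundant feature (2.82). Genes with the seed site lay below the random lists in the coding sequence (1.81), with a pseudocount of 0.1 (2.56) and over whole transcripts (1.88); the cause was not tested. No paired analysis was possible because each group has 1 library, and no library could be left out. In the input 9936 of 18499 genes had 0 reads, which does not separate low depth from lack of expression.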

Other observations

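The gene families here and all tests in this part were chosen after the results were seen, except those of base composition, of shared sequence and of the seed in abundant genes. The median over all listed genes was 7.76 pull-down RPKM, and over those with 0 input reads 8.08. The 721 olfactory receptor genes listed had 42 reads in the input and 28729 in the pull-down, with a pull-down median of 14.9 RPKM. The 161 vomeronasal receptor genes had 13 and 4820 reads and a median of 8.55 RPKM, and the 40 keratin genes had 0 and 658 reads and a median of 7.30 RPKM. Genes with long exons were higher in the pull-down: the median was 9.09 RPKM for a mean exon length above 1000 bases and 5.31 RPKM for one up to 150 bases. Ifnar1, a subunit of the type I interferon receptor noticed for its values, had 77 input and 3293 pull-down reads (34.5 against 639 RPKM).

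Pull-down reads lay at a similar level on genes with and without input reads. Capture through the miR-1 seed is argued against as the source of this level, since input-silent genes with no 6-base seed site had 0.996 times the median of those with one (8.05 against 8.09 RPKM). These sets were not matched on transcript length, and each input-silent gene listed has at least 1 pull-down read, which raises the RPKM floor of short genes. Base composition is argued against as the source of the low X chromosome, since X-linked genes stayed at 0.513 times autosomal lists matched on GC content. A candidate explanation is genomic DNA of male mice in the pull-down library, for which X-linked genes should lie near 0.5 of autosomal genes, and they lay at 0.493 (bootstrap over genes 0.428 to 0.591), and at 0.527 among genes with 0 input reads. The 14 Y-linked genes listed had 25 input and 522 pull-down reads, and their pull-down median was 0.509 times that of autosomal genes. Y-linked reads go with male mice, although these genes are few and the labels do not give the sex. How reads with several matches were counted is not given either. The input ratio depends on the measure (0.90 for the median of genes with at least 5 input reads, where the pull-down has 0.436, and 0.564 for the mean RPKM of all genes, bootstrap 0.369 to 0.828). Capture outside the seed was not tested, and without a control pull-down the hypothesis stays open.

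In the pull-down 135 genes reached 100 RPKM, among them 12 olfactory receptor genes, and 40 of the 135 had no input read. A candidate explanation for part of them is repeated sequence: in the 127 with a transcript sequence, the median share of 25-base words also present in another gene was 6.47%, against 0.0479% to 0.519% in length-matched lists. For others it is weak, as 54 of the 127 had at most 5% shared words, Olfr856-ps1 among them with 1.62%, and 5 had 50% or more (3.94%, against 2.57% of other genes). Base pairing with miR-1 stays open, since the mean longest run of complementary bases was 7.59, just above length-matched lists (7.15 to 7.50), while the search for the sense strand gave 7.59 within its lists (7.31 to 7.67). Whether the input holds the same material could not be settled. The median input to pull-down read ratio of the members was 5.63 times the ratio of the summed reads of the other olfactory receptor genes. The bootstrap range of 2.47 to 8.21 redraws the members alone. It leaves out the counting error of the other olfactory receptor genes, which had 10 input reads.

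The 113 genes with 200 RPKM or more in the input, such as Psap and Ctsd, stood above other genes in the pull-down. Their pull-down median was 20.5 RPKM, against 6.33 to 10.8 RPKM in length-matched lists of input-silent genes, as input RNA carried over could give. The excess over the median of those lists was 12.1 RPKM, 3.15% of their median input level of 385 RPKM. It was not shared by all members. Of the 113 genes 90.3% had a pull-down read, while others, such as Rpph1 (2677 input RPKM) and Cd14 (594 input RPKM), had 0. Capture through the seed cannot be told apart from carry-over, since the 43 of the 113 genes with a 6-base site had a pull-down to input ratio 1.64 times that of the 67 without (bootstrap 0.978 to 3.03), too few genes to decide. These sets were not matched on transcript length, which was 2374 bases with a site and 1874 bases without at the median.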
